A study of Mus musculus with 17 samples.

How the data were processed

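Tumours of MCA205, a transplantable mouse fibrosarcoma line, were grown in C57BL/6 mice and injected with doxorubicin (DX, an anthracycline chemotherapeutic that damages DNA) or phosphate-buffered saline (PBS). Total RNA of the bulk tumour was hybridised to Illumina mouse BeadChips, which carry one probe sequence on many beads and give one colour per array. The 17 arrays fall into 6 groups by the labels: day 2 PBS (n = 3), day 2 DX (n = 2), day 7 PBS (n = 3), day 7 DX non-responders (n = 3), day 7 DX responders (n = 3) and day 10 DX responders (n = 3). A day 10 PBS group was not analysed here. Groups and replicate numbers were taken from the sample titles, and BeadChips from the labels' array positions.

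The authors deposited, per the file headers, one signal intensity and one detection p-value per probe and array, on the linear scale and before normalization. How that p-value was computed is not given in the sources used here, and it is read below as the share of the array's negative controls at least as bright as the probe. GenomeStudio 2011.1 is named in the submitters' processing notes, with no settings. A second deposited table holds the authors' processed intensity values of the same arrays. Each of its 17 columns ranked probes most like the array of its own label. Its column medians were 119.6 or 119.7, so it was on a linear scale with nearly the same median in each array. Whether the whole distributions were alike was not compared. Which steps gave it is not given in the sources used here.

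The signals were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with the negative-control mean and spread inferred from the detection p-values and an offset of 16, and were put on the log2 scale. The offset pulls the fold changes of dim probes towards 1. Of 45281 probes, the platform annotation gave one symbol to 34885, several to 18 and none to 10378. Symbols were looked up by gene ID in a RefSeq gene table of assembly GRCm38.p6, in which 34807 probes matched and 0 symbols changed, and the table served for names only. Probes with a detection p-value under 0.01 on at least 2 arrays were kept (17674 probes). Each gene was represented by its kept probe with the highest mean signal, and probes without a symbol were tested under their own identifier. This left 12451 features, called genes below, of which 10035 had a symbol and 2416 had none.

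All 17 arrays entered one limma fit of 6 group means with a mean-variance trend (11 residual degrees of freedom, 6.98 prior degrees of freedom), because groups hold 2 or 3 arrays. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called changed. There were 8 comparisons: DX against PBS on day 2, responders, non-responders and all DX tumours against PBS on day 7, responders against non-responders on day 7, day 10 against day 7 in responders, day 7 against day 2 in PBS tumours, and the difference of the DX effect between day 7 and day 2. Gene lists, 28 in number, were fixed from textbook knowledge. They cover chemokines and the CCR2 axis (the receptor Ccr2 and its ligands Ccl2, Ccl7 and Ccl12), immune cell types and processes, tumour-cell processes, and markers of tissue that a dissected tumour could carry along (skeletal muscle, skin epithelium, fat). Lists with at least 3 measured members were tested with camera at its preset correlation between genes of 0.01, adjusted over the lists within a comparison. The B cell and erythroid lists had 1 measured member each and were not tested as lists. Each list was tested again with a correlation estimated from the data and with fry, a rotation test that asks whether a list's genes move, on balance, one way. Where a probe was not detected on any array of the dimmer group, the fold change is given as a bound, from the mean of the brighter group to the mean, per dim array, of the higher of the probe's own value and the lowest detected signal. Where the gene was not detected in either group, or that bound fell under 1, no fold is given; Ccr2 falls under this after day 2, and the medians of its list include it.

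The genes named in the text follow a rule: the 10 largest rises and the 10 largest falls among called genes with a gene name whose probe was detected on every array of the brighter group, and up to 4 called members of each list that camera called or that had at least 3 called members. The 4 members of the CCR2 axis were always given (Ccr2 by its detection alone after day 2), and where no gene was called the 5 genes with the smallest p in each direction were given. Other list members named in the text serve as examples of their list and are given with their values. The design, the lists, the naming rule and all alternatives except one were chosen before the data were examined.

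Fits and list tests were tested on simulated data with the real means and spreads of the 12451 genes. In the simulated day 2 comparison 71.6% of the genes changed by 1 on the log2 scale were called and 11.9% of those changed by 0.5. In the simulated comparison of day 7 responders with PBS the shares were 85.1% and 8.96%, and in that of all day 7 DX tumours with PBS 92.5% and 23.9%. Every gene changed by 2 was called in each of these 3 simulations, and 4, 8 and 6 unchanged genes were called. Of 24 unshifted lists 0 were called by camera in each simulation. The genes were drawn independently of each other and without a BeadChip or tissue effect. This count thus does not show how often camera calls unshifted lists among the correlated genes of real arrays.

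The alternatives were no background correction, normexp without the detection p-values (offset 50), the authors' processed values, no filter or a stricter filter on dim probes (detection on at least 6 arrays), every probe tested by itself, the BeadChip as a fixed or random block, single BeadChips, the replicate number as a block, a fit without the mean-variance trend, array weights, a fit of the compared groups alone, one pooled day 7 DX group, and each array left out in turn. The groups are spread unevenly over 3 BeadChips, so BeadChip-blocked and within-BeadChip values stand beside the results. Both PBS groups lie on BeadChips 2 and 3, day 2 DX on 1 and 3, non-responders on 1 and 2, and both responder groups on 1 and 3. BeadChip 1 thus holds 0 PBS arrays and BeadChip 2 holds 0 responder arrays, so treatment and outcome are partly confounded with the BeadChip. Day 7 responders and PBS share only BeadChip 3, with 1 array each. Called genes were selected on these same arrays, so a direction kept within a BeadChip is largely fixed by that selection. The number of arrays limits the precision.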

Results

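The transcripts of whole MCA205 fibrosarcomas were measured on 17 arrays, 1 per tumour sample. Tumours had been injected with PBS or DX and were taken on day 2 (PBS n = 3, DX n = 2), on day 7 (PBS n = 3, DX n = 6) or on day 10 (DX n = 3). The 6 DX samples of day 7 were labelled by the course of the tumour as 3 responders and 3 non-responders, and the day 10 samples as responders. Per array, 13728 to 15568 of 45281 probes were detected and the median signal was 105.8 to 135.5. Day 7 PBS replicates 2 and 3 had the fewest detected probes (14004 and 13728, against 14070 to 14917 in day 7 responders). Their 75th signal percentiles (133.3 and 138.5) were the lowest, against 151.6 to 172.9 in those responders and 156.7 in day 7 PBS replicate 1. Their lowest detected log2 signals (5.37 and 5.43) were the highest of the 17 arrays and enter the fold-change bounds. Whether this signal range affected the day 7 comparisons was not tested. Replicates of a group correlated with r from 0.965 to 0.991 across genes. The p-values here measure the spread between these samples, which the labels do not describe as separate animals. The series set out to follow recruitment of antigen-presenting cells through the chemokine CCL2 and its receptor CCR2 after chemotherapy, so the genes of this axis are given in every comparison.

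Replicate 3 of the day 7 responders and replicate 3 of the day 10 responders carried skeletal muscle transcripts far above the other 15 arrays. All 16 measured muscle markers lay more than 1 log2 unit above the mean of those arrays on both, with a median difference of 5.29. Myl1, a myosin light chain of fast muscle, had a mean log2 signal of 7.76 on the other arrays and 14.38 and 14.16 on these. Acta1, skeletal muscle actin, had 7.28 against 13.39 and 13.10. Among the other arrays Acta1 reached 10.51 on day 10 responder replicate 1. It had 9.11 and 7.60 on day 7 responder replicates 1 and 2, and 4.79 to 6.24 on the day 7 PBS and non-responder arrays. Krt14, a keratin of basal epidermis, was also bright on these arrays (12.92 and 11.72), on non-responder replicate 2 (12.11) and on day 2 PBS replicate 3 (10.22). It had 9.08 on day 7 responder replicate 2 and 8.87 and 9.99 on day 10 replicates 1 and 2, and lay between 4.63 and 7.00 on the other 10 arrays, among them day 7 responder replicate 1 (6.48). Gene group medians of the responder comparisons are therefore also given without the muscle-rich arrays.

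On day 2, genes of the type I interferon response, the antiviral programme set off by interferons alpha and beta, rose after DX. Of 22 measured members 13 were called higher over all genes and 22 when adjusted over the list alone, with a median log2 difference of 1.34. Mx1, an antiviral GTPase, rose 3.66-fold (log2 1.87 ± 0.31 SE, adjusted p = 0.00545), and Irf7, a transcription factor that amplifies the response, rose 3.10-fold (1.63 ± 0.20, adjusted p = 3.27e-04). Ifi205, an interferon-inducible protein of the nucleic acid sensing family, rose 3.58-fold (1.84 ± 0.21, adjusted p = 1.53e-04) and the ubiquitin-like Isg15 2.89-fold (1.53 ± 0.22, adjusted p = 0.00117). Rsad2 (log2 1.70), Oasl1 (1.55), Cmpk2 (1.75), Phf11a (1.58) and Tgtp1 (1.28) were also called higher. Ifnb1, which encodes interferon beta itself, was detected on none of the 3 PBS arrays and on both DX arrays, at least 2.28-fold higher (adjusted p = 0.0186). Every named gene that rose was higher on 2 of 2 DX arrays than on any day 2 PBS array. The list was called by camera (adjusted p = 6.07e-58; adjusted p = 0.00381 with an estimated correlation) and was the only list on day 2 called with the estimated correlation and by fry. Its median was 1.33 with the BeadChip as a block and 1.13 within BeadChip 3.

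The ligands of CCR2 were higher on both day 2 DX arrays than on any of the 3 PBS arrays, without passing the adjustment over all genes. Ccl7 was 2.01-fold higher (mean log2 signal 11.20 ± 0.08 SD in PBS and 12.21 ± 0.18 in DX, adjusted p = 0.0773), Ccl2 1.92-fold (9.97 ± 0.07 and 10.92 ± 0.30, adjusted p = 0.322) and Ccl12 1.81-fold (9.90 ± 0.29 and 10.75 ± 0.02, adjusted p = 0.189, and 0.0463 with the BeadChip as a block). Ccr2 itself differed by -0.15 (adjusted p = 0.999), near the detection limit, and was detected on 2 of 3 PBS and 2 of 2 DX arrays. With the compared groups alone in the fit all 3 ligands were called (adjusted p = 3.87e-04, 0.00207 and 0.0107), as they were with array weights, while over the alternatives the adjusted p of each reached 1. Adjusted over the list alone, 3 of the 4 genes were called higher. As a list the axis had a median of 0.90 (camera adjusted p = 2.16e-04; adjusted p = 0.0813 with an estimated correlation), 0.99 with the BeadChip as a block and 0.73 within BeadChip 3.

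**Figure D1:**
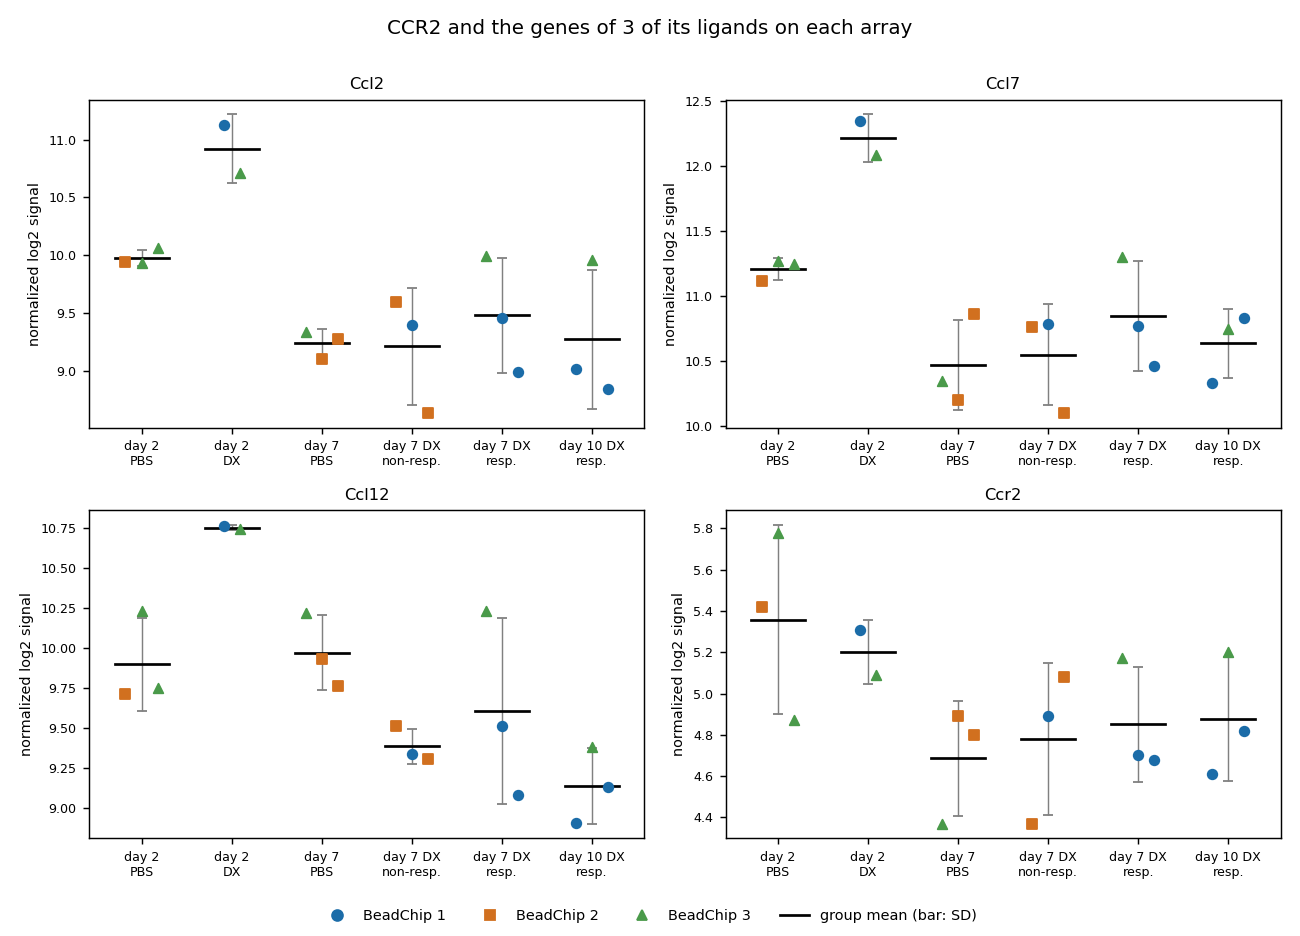
Normalized log2 signal of Ccl2, Ccl7, Ccl12 and Ccr2 on each of the 17 arrays by group, with symbols for the BeadChip, horizontal lines for group means and bars for the SD. Both day 2 DX arrays lie above all day 2 PBS arrays for the 3 ligands, and Ccl2 and Ccl7 have lower means in every day 7 and day 10 group.

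Among the other chemokines, Cxcl10, an interferon-induced attractant of T cells, rose 2.90-fold (1.53 ± 0.23, adjusted p = 0.00167) and Ccl4 2.76-fold (1.46 ± 0.21, adjusted p = 0.00121). The chemokine list of 21 genes, which holds the 3 CCR2 ligands, had 2 called members, 7 when adjusted over the list alone, and a median of 0.45 (camera adjusted p = 1.63e-08; adjusted p = 0.072 with an estimated correlation; 0.39 with the BeadChip block, 0.23 within BeadChip 3). Interferon gamma response genes had a median of 0.84, with 2 of 15 called and 8 called when adjusted over the list alone (camera adjusted p = 1.1e-14; adjusted p = 0.0813 with an estimated correlation; 0.80 with the block, 0.55 within BeadChip 3). MHC class I presentation genes were positive in 14 of 14 members with a median of 0.46 (camera adjusted p = 8.1e-09; adjusted p = 0.0813 with an estimated correlation; 0.49 with the block, 0.36 within BeadChip 3). MHC class II presentation genes went the other way, with a median of -0.37 (camera adjusted p = 0.0169; adjusted p = 0.526 with an estimated correlation; -0.17 within BeadChip 3). That call ended with the BeadChip block (0.0501) and without day 2 PBS replicate 1 (0.239), PBS replicate 3 (0.06) or DX replicate 2 (0.0701). Lists of monocyte and macrophage markers (median -0.07, camera adjusted p = 0.985), dendritic cell and costimulation markers (-0.01, 0.956) and T and NK cell markers (-0.04, 0.956) did not pass.

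The largest falls on day 2 were in the adult globin genes Hbb-bs, Hbb-bt and Hba-a1, which encode the haemoglobin chains of red blood cells. Hbb-bs was 7.55-fold lower (log2 -2.92 ± 0.49, adjusted p = 0.00569), Hbb-bt 6.60-fold (-2.72 ± 0.52, adjusted p = 0.016) and Hba-a1 5.83-fold (-2.54 ± 0.51, adjusted p = 0.0226). Hba-a1 was the 1 measured member of the erythroid list, and Fcrla, the 1 measured B cell marker, differed by -0.26 (adjusted p = 0.999). The transferrin receptor Tfrc (-0.91 ± 0.18, adjusted p = 0.0172), the tRNA exporter Xpot (-0.73 ± 0.12, adjusted p = 0.00292), the amino acid transporter Slc7a3 (-0.83), the isoleucyl-tRNA synthetase Iars (-0.59) and Rangrf (-0.58) were lower on both DX arrays. Targets of p53, the DNA damage response factor, had a median of 0.07 with 1 of 25 called when adjusted over the list alone (camera adjusted p = 0.0224; adjusted p = 0.271 with an estimated correlation; 0.03 within BeadChip 3). The example Cdkn1a, a cell cycle inhibitor, stood at 0.96 (adjusted p = 0.13). The p53 call ended with the BeadChip block (0.0841) and without PBS replicate 1 (0.0931) or DX replicate 1 (0.138).

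In all, limma called 66 genes higher and 10 lower of 12451 on day 2, and camera called 11 of 26 lists. With the BeadChip as a block 57 genes were called, and all 76 genes called without it kept their direction within BeadChip 3. The count was 46 without PBS replicate 2, 36 without PBS replicate 3 and 11 without DX replicate 1, which leaves 1 DX array that is assumed to vary like the other groups. Ifi205 and Irf7 were the 2 of 20 named called genes that passed without DX replicate 1, and 13 of the 20 passed with the block, with Ifnb1 (0.071), Tfrc (0.0548) and Hba-a1 (0.0538) among those that did not.

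On day 7 the question was which transcripts differed between DX tumours that responded and PBS tumours. Of the 23 named called genes 0 passed with the BeadChip as a block or without any one of the 6 arrays except PBS replicate 3, without which 17 passed. Among those higher in responders, Klrd1, an NK cell receptor subunit, rose 2.73-fold (1.45 ± 0.28, adjusted p = 0.0385), Nkg7, a cytotoxic granule protein, 2.91-fold (1.54 ± 0.33, adjusted p = 0.0458), and the granule-associated protease Ctsw (log2 1.33), the NK receptors Klre1 (1.67) and Klra7 (1.54) and the cytokine receptor Il18r1 (1.47) rose with them. Satb1, a chromatin organiser of T cell development, rose 3.71-fold (1.89 ± 0.35, adjusted p = 0.0343) and Slpi, a secreted protease inhibitor, 2.98-fold (1.58 ± 0.27, adjusted p = 0.0343). Fst, which binds activin, was at least 2.55-fold higher, the clotting factor gene F10 at least 2.03-fold, and Nppb (1.77), Prl2c2 (1.55) and the antiviral Oas2 (1.25) were also called. The adjusted p of these genes lay between 0.0343 and 0.0471, and each was higher on 3 of 3 responder arrays than on any day 7 PBS array.

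Of 12 T and NK cell markers 2 were called in responders, 5 when adjusted over the list alone, with a median of 0.59 (camera adjusted p = 3.37e-06; adjusted p = 0.159 with an estimated correlation; fry adjusted p = 0.0352). Its median was 0.52 with the BeadChip block, 1.02 within BeadChip 3 and 0.70 without the muscle-rich array. Cytotoxic effectors (median 0.78, 3 of 5 adjusted over the list alone) and immune checkpoints (0.72, 7 of 8 adjusted over the list alone) were called too (camera adjusted p = 9.52e-05 and 1.38e-05), each at adjusted p = 0.159 with an estimated correlation. Their medians were 0.67 and 0.55 with the block, 0.90 and 0.82 within BeadChip 3, and 0.71 and 0.82 without the muscle-rich array. Checkpoint genes included Ctla4 (1.17, adjusted p = 0.055) and Cd274, which encodes PD-L1 (0.96). Interferon gamma response genes had a median of 0.61, with 11 of 15 called when adjusted over the list alone (camera adjusted p = 1.44e-07; adjusted p = 0.179 with an estimated correlation; 0.60 with the block, 1.02 within BeadChip 3, 0.62 without the muscle-rich array). The skeletal muscle list moved in the same comparison (median 2.19, camera adjusted p = 5.29e-07; adjusted p = 0.371 with an estimated correlation), as did skin epithelium markers (0.75, 9.82e-04, and 0.418 with an estimated correlation). Without replicate 3 of the responders these 2 calls ended (0.0544 and 0.368), while the adipocyte list did not pass in any comparison with all arrays. Within BeadChip 3 the muscle and skin medians were 0.53 and 0.17. The CCR2 axis list did not pass: Ccl7 differed by 0.38 (adjusted p = 0.45), Ccl2 by 0.24 (0.731) and Ccl12 by -0.36 (0.47). The list median was 0.20, 0.31 with the block and 0.73 within BeadChip 3, where Ccl7 differed by 0.96, Ccl2 by 0.65 and Ccl12 by 0.01. Ccr2 was not detected on any PBS, responder or non-responder array of day 7, so it is given no difference within that day.

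Enzymes of cholesterol synthesis were among the falls in responders, including Nsdhl (-0.95, adjusted p = 0.0404), Cyp51 (-0.79, 0.0404), Fdps (-0.67, 0.0404) and Sqle (-0.54, 0.0451). Chac1, a glutathione-degrading enzyme induced by ER stress, fell by 1.13 on the log2 scale (adjusted p = 0.0404) and was the called member of the ER stress and heat shock list. That list had 8 of 22 members lower and 1 higher when adjusted over the list alone, with a median of -0.27 (camera adjusted p = 1.57e-04; adjusted p = 0.159 with an estimated correlation; -0.24 with the block, -0.40 within BeadChip 3, -0.26 without the muscle-rich array). Fcrls, an Fc receptor-like gene of macrophages, had the largest named fall, 4.62-fold (-2.21 ± 0.48, adjusted p = 0.0471). Idh1 (-0.73), Tmem184c (-0.89), the glucocorticoid-induced Tsc22d3 (-0.97) and the transcription factor Osr2 (-1.04) were also lower on 3 of 3 responder arrays.

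Over all genes limma called 53 higher and 13 lower in responders. With the BeadChip as a fixed block 0 were called by limma (749 at unadjusted p under 0.05, smallest adjusted p = 0.219). With that block the median size of the 66 genes called without it went from 1.14 to 0.92 and the median SE from 0.22 to 0.25, with 66 of 66 in the same direction. As a random block it left 23 genes called. The count was 0 without PBS replicate 1, PBS replicate 2, or any one of the 3 responders, and 78 without PBS replicate 3. Without the muscle-rich array limma called 0 (1395 at unadjusted p under 0.05). All 66 genes kept their direction within BeadChip 3, which holds 1 array of each group. They were selected on these same arrays, so this is no separate test against the BeadChip.

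DX tumours that did not respond differed from PBS by 13 genes higher and 3 lower, of which 5 had a symbol. Tmem164, a membrane protein gene (0.95, adjusted p = 0.0105), and Nfat5, the transcription factor of the response to osmotic stress (0.60, adjusted p = 0.0228), rose, as did the adhesion protein gene Flrt3, at least 1.83-fold (adjusted p = 0.03). Sntb2 rose (1.10 ± 0.15, adjusted p = 0.0105), although 0 of its 2 other probes went the same way. The sterol enzyme gene Nsdhl fell by 1.01 on the log2 scale (adjusted p = 0.0361, and 0.075 with the BeadChip block). Each was beyond all PBS values on 3 of 3 non-responder arrays. Monocyte and macrophage markers had a median of -0.29 with 5 of 18 lower when adjusted over the list alone (camera adjusted p = 5.5e-04; adjusted p = 0.652 with an estimated correlation), -0.29 with the block and -0.34 within BeadChip 2. Examples are Csf1r, the receptor of a macrophage growth factor (-0.74), the complement gene C1qa (-0.71) and Cx3cr1 (-1.07). MHC class II genes had a median of -0.30 (camera adjusted p = 0.00383; adjusted p = 0.652 with an estimated correlation; -0.39 with the block, -0.59 within BeadChip 2), and the call ended without non-responder replicate 3 (0.18). In the CCR2 axis, Ccl12 differed by -0.58 (adjusted p = 0.341), Ccl2 by -0.02 (0.984) and Ccl7 by 0.08 (0.919), and Ccr2 was not detected on any array of either group. Within BeadChip 2 the ligands differed by -0.43, -0.07 and -0.10 in that order.

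With the BeadChip block 14 genes were called in non-responders, and 16 of 16 kept their direction within BeadChip 2. The count was 0 without PBS replicate 1, PBS replicate 2 or non-responder replicate 2, 52 without non-responder replicate 1 and 8 without non-responder replicate 3. Calls of the cell cycle list (-0.13, camera adjusted p = 0.0298; adjusted p = 0.652 with an estimated correlation) and the interferon gamma list (0.31, 0.0298 and 0.652) ended without non-responder replicate 2 (0.0603 and 0.48). The first also ended without PBS replicate 3 (0.238) or non-responder replicate 3 (0.0767), and the second without PBS replicate 1 (0.27), PBS replicate 2 (0.317) or with the block (0.0681). Within BeadChip 2 the medians were -0.12 and 0.02.

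Taking all 6 DX samples of day 7 together, 30 genes were higher and 7 lower than in PBS. Tmem164 (0.88, adjusted p = 0.00436) and Sntb2 (0.97, adjusted p = 0.00436) had the smallest adjusted p of the named genes, and 1 of the 2 other probes of Sntb2 went the same way. Slpi (1.34 ± 0.24, adjusted p = 0.0187), Prl2c2 (1.30, 0.0128), Rcan1 (0.79), Hao1 (0.79) and Smg1 (0.64) rose, and Flrt3 (at least 1.77-fold), Fst (at least 2.04-fold) and Il13ra2 (at least 1.5-fold) were higher against PBS arrays on which they were not detected. The named falls were all in cholesterol synthesis: Nsdhl (-0.98), Cyp51 (-0.76 ± 0.14, adjusted p = 0.0187), Fdps (-0.61) and Sqle (-0.47). Each named gene was beyond all PBS arrays on 6 of 6 DX arrays, except Rcan1 on 5. With the BeadChip block 6 genes were called, Sntb2 (0.0251) and Tmem164 (0.0191) among them, and the median size of the 37 genes went from 0.91 to 0.84. All 37 kept their direction within BeadChips 2 and 3, but they were selected on these same arrays, so this is no separate test. The count was 8 without PBS replicate 1, 0 without PBS replicate 2, 18 without non-responder replicate 2, 20 and 21 without responder replicates 2 and 3, 105 without non-responder replicate 1 and 68 without non-responder replicate 3.

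T and NK cell markers had a median of 0.39 over the 6 DX samples (camera adjusted p = 0.00123; adjusted p = 0.388 with an estimated correlation), 0.31 with the BeadChip block, 0.43 without the muscle-rich array, -0.07 within BeadChip 2 and 1.02 within BeadChip 3. Interferon gamma response genes had 0.47 (3.31e-05, and 0.388 with an estimated correlation), 0.30 with the block, 0.43 without the muscle-rich array, 0.02 within BeadChip 2 and 1.02 within BeadChip 3. In BeadChip 2 the DX samples were non-responders and in BeadChip 3 a responder. Monocyte and macrophage markers were called lower by camera, though not with an estimated correlation. Their call ended without PBS replicate 3 (median -0.12, camera adjusted p = 0.24). Skeletal muscle and skin epithelium markers were called by camera in the same comparison. Both calls ended without responder replicate 3 (medians 0.24 and 0.28, camera adjusted p = 0.325 each). In the CCR2 axis, Ccl7 differed by 0.23 (adjusted p = 0.598), Ccl2 by 0.11 (0.87) and Ccl12 by -0.47 (0.257), and Ccr2 was not detected. Within BeadChip 2 the ligands differed by -0.10, -0.07 and -0.43 in that order, and within BeadChip 3 by 0.96, 0.65 and 0.01. Responders and non-responders were set against the same 3 PBS samples, so their differences share chance values. Their log2 differences correlated with r = 0.65 across genes, where unchanged groups against these controls gave 0.50 in 100 simulations. The covariance was 0.0673 against 0.0264 simulated. Both comparisons called 9 genes higher (0.0553 for independent calls) and 3 lower (0.00313). The 3 controls cannot be split with 2 in each part, so some of the excess may come from the shared controls. The simulations held no BeadChip effect. BeadChip 1 holds 2 responder, 1 non-responder and 0 day 7 PBS arrays, so some of the excess may also come from the BeadChip.

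Responders and non-responders of day 7 were compared directly to ask what separates DX tumours by outcome. No single gene passed: limma called 0 of 12451, with 711 at unadjusted p under 0.05 against 623 by chance and a smallest adjusted p of 0.376. With the compared groups alone in the fit 1 gene was called, Osr2, and all other settings called 0. Osr2 was lower on 3 of 3 responder arrays (-1.21 ± 0.22, adjusted p = 0.376, and 0.0241 in that fit). The other genes with the smallest p were the transport regulator Fxyd6 (1.87), troponin C Tnnc1 (1.28), Tmem51 (0.81), the macrophage gene Aif1 (0.72) and Ass1 (0.66) on the higher side, and the matrix proteases Mmp11 (-0.73) and Mmp2 (-0.37), Wls (-0.63) and Igfbp4 (-0.52) on the lower side. None of these 9 passed (adjusted p = 0.687). In the CCR2 axis, Ccl7, Ccl2 and Ccl12 differed by 0.29, 0.27 and 0.22, with adjusted p of 0.89 or more, and Ccr2 was not detected in either group. The axis list did not pass (median 0.24, camera adjusted p = 0.116) but was called without the muscle-rich array (0.48, 0.00465). It had the opposite sign within BeadChip 1, with a median of -0.17 and 0 of 4 members positive, and 0.19 with the block.

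Gene lists were compared as responders minus non-responders, and 0 of those called by camera were called with an estimated correlation. T and NK cell markers had a median of 0.54, with 3 of 12 higher when adjusted over the list alone (camera adjusted p = 4.95e-06; adjusted p = 0.162 with an estimated correlation). The median was 0.50 with the BeadChip block, 0.57 without the muscle-rich array and 0.05 within BeadChip 1, which holds 1 non-responder and 2 responders. Cytotoxic effectors had 0.66 (camera adjusted p = 2.3e-04; adjusted p = 0.162 with an estimated correlation) with 0.58 under the block, 0.70 without the muscle-rich array and 0.29 within BeadChip 1. Of 20 extracellular matrix genes 8 were lower and 1 higher when adjusted over the list alone, with a median of -0.35 (camera adjusted p = 2.57e-07; adjusted p = 0.0848 with an estimated correlation). That median was -0.30 with the block, -0.34 within BeadChip 1 and -0.30 without the muscle-rich array, and examples are the collagen Col5a2 (-0.86), periostin Postn (-0.78) and fibronectin Fn1 (-0.74). Cell cycle genes were positive in 28 of 32 members with a median of 0.17 (camera adjusted p = 1.03e-06; adjusted p = 0.0848 with an estimated correlation; 0.23 with the block, 0.16 within BeadChip 1, 0.21 without the muscle-rich array). Dendritic cell and costimulation markers had 0.37 (camera adjusted p = 0.00443; adjusted p = 0.0848 with an estimated correlation), 0.26 with the block, 0.41 without the muscle-rich array and 0.04 within BeadChip 1. Camera also called monocyte and macrophage markers higher, with list means of -0.06 in responders, -0.20 in non-responders and 0.09 in day 7 PBS. That call ended without responder replicate 1 (median 0.06, camera adjusted p = 0.26). MHC class II genes had 0.31 (camera adjusted p = 5.41e-04; adjusted p = 0.233 with an estimated correlation), 0.39 with the block, 0.31 without the muscle-rich array and the opposite sign within BeadChip 1 (-0.09), and that call ended without non-responder replicate 3 (0.131) or responder replicate 1 (0.142).

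Skeletal muscle markers moved with these groups, with a median of 2.26 (camera adjusted p = 2.22e-11; adjusted p = 0.19 with an estimated correlation) and 0.58 without the muscle-rich array, and skin epithelium markers had 0.59, or 0.05 without it and 0.08 with the block. Camera called 18 lists, 16 higher and 2 lower, of which 0 were called by fry. Of the 18 calls 9 held without any one array. The list levels on each array place responder replicates 1 to 3 above the PBS arrays for T and NK cell markers, with non-responder replicate 2 among them.

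**Figure D2:**
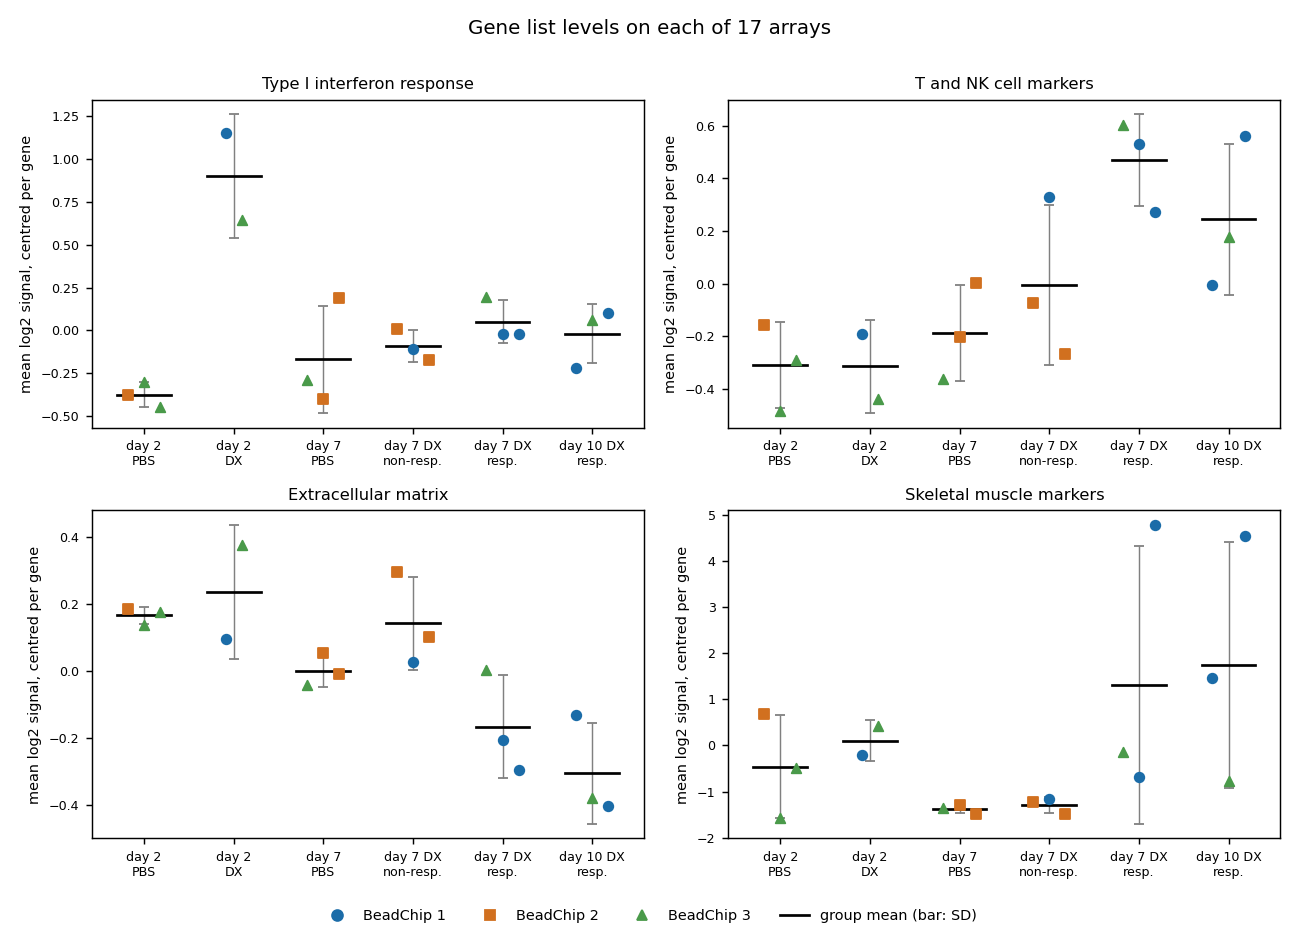
Mean log2 signal, centred per gene, of the type I interferon response, T and NK cell, extracellular matrix and skeletal muscle lists on each of the 17 arrays by group, with symbols for the BeadChip, lines for group means and bars for the SD. The type I interferon mean is 0.90 in day 2 DX and -0.37 in day 2 PBS, and the muscle level reaches 4.76 and 4.53 on single responder arrays of day 7 and day 10.

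Between day 7 and day 10 in responders, 1 gene was called, Abcc3, which encodes an organic anion export pump. It fell by 1.23 on the log2 scale (SE 0.18, adjusted p = 0.0308), on 3 of 3 day 10 arrays. It passed without day 10 replicate 1 and not without any other single array or with the BeadChip block (adjusted p = 0.0761). ER stress and heat shock genes had a mean log2 signal, centred per gene, of -0.20 in day 7 and 0.19 in day 10 responders. It was 0.09 in day 7 PBS and 0.02 in non-responders. The low day 7 responder level, which also gave the fall of this list against PBS, thus enters the rise to day 10. In that rise 22 of 22 members were positive with a median of 0.29, 2 of them higher when adjusted over the list alone (camera adjusted p = 1.18e-13, adjusted p = 0.0161 with an estimated correlation, fry adjusted p = 0.0705). The median was 0.19 within BeadChip 1, 0.49 within BeadChip 3 and 0.38 without the muscle-rich arrays, and examples are the heat shock gene Hspa1a (1.14) and the stress factor Atf3 (1.03), each at adjusted p = 1. Monocyte and macrophage markers had a median of -0.25 (camera adjusted p = 3.35e-05; adjusted p = 0.373 with an estimated correlation), 0.01 within BeadChip 1, -0.72 within BeadChip 3 and -0.33 without the muscle-rich arrays, a call that ended without day 7 replicate 1 (0.0655) or day 10 replicate 2 (0.0748). Ccl12 differed by -0.46, and Ccl2 and Ccl7 by -0.21, all at adjusted p = 1, while Ccr2 was not detected on either day. The axis list did not pass (median -0.21, camera adjusted p = 0.184) but was called without the muscle-rich arrays (-0.37, 0.017). Within BeadChip 3 its median was -0.29, and within BeadChip 1 Ccl12, Ccl2 and Ccl7 differed by -0.27, -0.30 and -0.04. No PBS group of day 10 was analysed here, so time and DX are not separated in this comparison.

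Tumours given PBS changed between day 2 and day 7, the background against which DX effects on the 2 days stand. The largest named rises were in the granzyme genes Gzmg, 8.36-fold (3.06 ± 0.55, adjusted p = 0.014), and Gzmd, 5.87-fold (2.55 ± 0.52, adjusted p = 0.0302). The cytotoxic effector list, to which neither belongs, did not pass (median 0.06, camera adjusted p = 0.35; 0.52 within BeadChip 2 and -0.17 within BeadChip 3). Of 19 hypoxia and glycolysis genes 6 were called higher and 13 when adjusted over the list alone, with a median of 0.52 (camera adjusted p = 2.4e-12; adjusted p = 0.166 with an estimated correlation; fry adjusted p = 0.0149). Among them Car9, a carbonic anhydrase induced by low oxygen, rose 3.36-fold (1.75 ± 0.34, adjusted p = 0.0225), and Aldoc, a glycolytic aldolase, by 1.42 ± 0.17 (adjusted p = 5.4e-04). P4ha1 (1.16), the glucose transporter gene Slc2a1 (0.99) and Pfkfb3 (at least 1.27-fold) rose as well. Outside the list Mgarp (1.45), Gpnmb (1.36), the costimulatory receptor Tnfrsf9 (1.36), Plxdc1 (1.19) and the histone gene H2ac18 (1.12) rose. The hypoxia median was 0.46 with the BeadChip block and 0.61 and 0.43 within BeadChips 2 and 3.

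Among the falls over the same days, Saa3, an acute-phase protein gene, was 7.48-fold lower (-2.90 ± 0.48, adjusted p = 0.0106), Rarres2, which encodes chemerin, 6.55-fold (-2.71 ± 0.43, adjusted p = 0.00707; 1 of its 2 other probes went the same way), and haptoglobin Hp at least 3.29-fold. The monocyte attractant Ccl8 fell 4.52-fold (-2.17 ± 0.38, adjusted p = 0.0124), and Gpx3 (-1.88), Prl2c2 (-1.41), the cystine transporter Slc7a11 (-1.37), Tmem164 (-1.31), Pde4b (-1.24) and Papss2 (at least 2.03-fold) fell too. The chemokine list had a median of -0.18 (camera adjusted p = 0.0355; adjusted p = 0.475 with an estimated correlation), -0.13 and -0.27 within BeadChips 2 and 3. That call ended with the BeadChip block (0.0643), without day 2 replicate 2 (0.0952) or without day 7 replicates 1 (0.131) or 2 (0.165). Each named called gene was beyond all day 2 arrays on 3 of 3 day 7 arrays. The CCR2 axis list had a median of -0.70 with 3 of 4 lower when adjusted over the list alone (camera adjusted p = 0.0294; adjusted p = 0.348 with an estimated correlation). Ccl7 differed by -0.74 (adjusted p = 0.121), Ccl2 by -0.73 (0.225) and Ccl12 by 0.07 (0.916), and Ccl2 (0.0113) and Ccl7 were called with the compared groups alone in the fit, Ccl7 also with array weights (0.037). Ccr2 was detected on 2 of 3 day 2 arrays and 0 of 3 day 7 arrays and is given no fold, and the 3 ligands alone had a median of -0.73. The axis call ended with the BeadChip block (0.0643), without day 2 replicate 2 (0.0951) or without day 7 replicates 1 (0.0878) or 2 (0.0586). Its medians within BeadChips 2 and 3 were -0.58 and -0.79. MHC class II genes were negative in 11 of 11 members with a median of -0.55 (camera adjusted p = 1.27e-04; adjusted p = 0.323 with an estimated correlation; -0.61 with the block, -0.65 and -0.43 within BeadChips 2 and 3). Endothelial markers had -0.39 (camera adjusted p = 0.00111; adjusted p = 0.348 with an estimated correlation) and mast cell and eosinophil markers -0.66 (0.00505, and 0.204 with an estimated correlation). With the block these medians were -0.40 and -0.71. Within BeadChips 2 and 3 they were -0.52 and -0.28 for endothelial and -0.89 and -0.61 for mast cell markers. Skeletal muscle transcripts did not pass, with a median of -0.78 (camera adjusted p = 0.103, and 0.0133 with the block), -1.77 within BeadChip 2 and -0.25 within BeadChip 3. Acta1 had log2 signals of 9.85, 4.78 and 8.27 on the day 2 PBS arrays and 5.27, 5.55 and 5.46 on day 7, so day 2 replicate 2 lay below all 3 day 7 arrays.

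In PBS tumours 40 genes were higher and 39 lower on day 7, and 77 were called with the BeadChip block. All 79 kept their direction within BeadChips 2 and 3. The count was 8 without day 2 replicate 1, 41 without day 2 replicate 3, and 29 and 32 without day 7 replicates 2 and 3. Aldoc, Gpnmb, Tmem164 and Papss2 were the 4 of 22 named called genes that passed without day 2 replicate 1.

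The effect of DX was then compared between the days by testing the difference itself, day 7 (both outcomes) minus day 2. Interferon response genes had a smaller DX effect on day 7 than on day 2: 22 of 22 members were negative with a median of -1.16, 7 were called and 19 when adjusted over the list alone (camera adjusted p = 9.47e-33; adjusted p = 0.0364 with an estimated correlation; fry adjusted p = 0.0094). The median was -0.59 within BeadChip 3 and -1.10 without the muscle-rich array. On day 7 itself camera called the type I interferon list higher in responders (list mean 0.05) than in PBS (-0.17) and non-responders (-0.09). With an estimated correlation neither was called. The first call ended without PBS replicate 1 (0.153), PBS replicate 2 (0.301) or responder replicate 1 (0.214). The second ended without non-responder replicate 2 (0.0807), non-responder replicate 3 (0.131) or responder replicate 1 (0.339). Mx1 differed from PBS by 1.87 on day 2 and -0.44 on day 7 (difference -2.31 ± 0.40, adjusted p = 0.0168), Isg15 by 1.53 and -0.14 (adjusted p = 0.0143) and Irf7 by 1.63 and 0.28 (adjusted p = 0.0288). The globin gene Hbb-bs went from -2.92 to 1.24 (difference 4.16 ± 0.62, adjusted p = 0.0092), and Tmem164 from -0.42 to 0.88 (adjusted p = 0.0129). For the CCR2 ligands the differences were -1.33 for Ccl12 (adjusted p = 0.113, 0.0242 with the BeadChip block and 0.0127 without responder replicate 1), -0.83 for Ccl2 (0.61) and -0.78 for Ccl7 (0.497), and Ccr2, not detected on any day 7 array, is given no difference. The axis as a list had a median of -0.81 (camera adjusted p = 0.00488; adjusted p = 0.431 with an estimated correlation), -0.83 over the ligands alone, -0.70 without the muscle-rich array and 0.03 within BeadChip 3, which holds 1 responder and where Ccl12, Ccl2 and Ccl7 had -0.74, -0.06 and 0.13.

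Limma called 11 genes with a positive and 17 with a negative difference, split 6 and 20 without background correction and 7 and 20 in the authors' processed values. With the BeadChip block 37 were called, and 28 of 28 kept their direction within BeadChip 3. The count was 1 without day 2 DX replicate 1, with 0 of 14 named genes passing, 13 without DX replicate 2, 14, 18 and 15 without day 2 PBS replicates 1, 2 and 3, and 12, 17 and 16 without day 7 PBS replicates 1, 2 and 3.

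**Figure D3:**
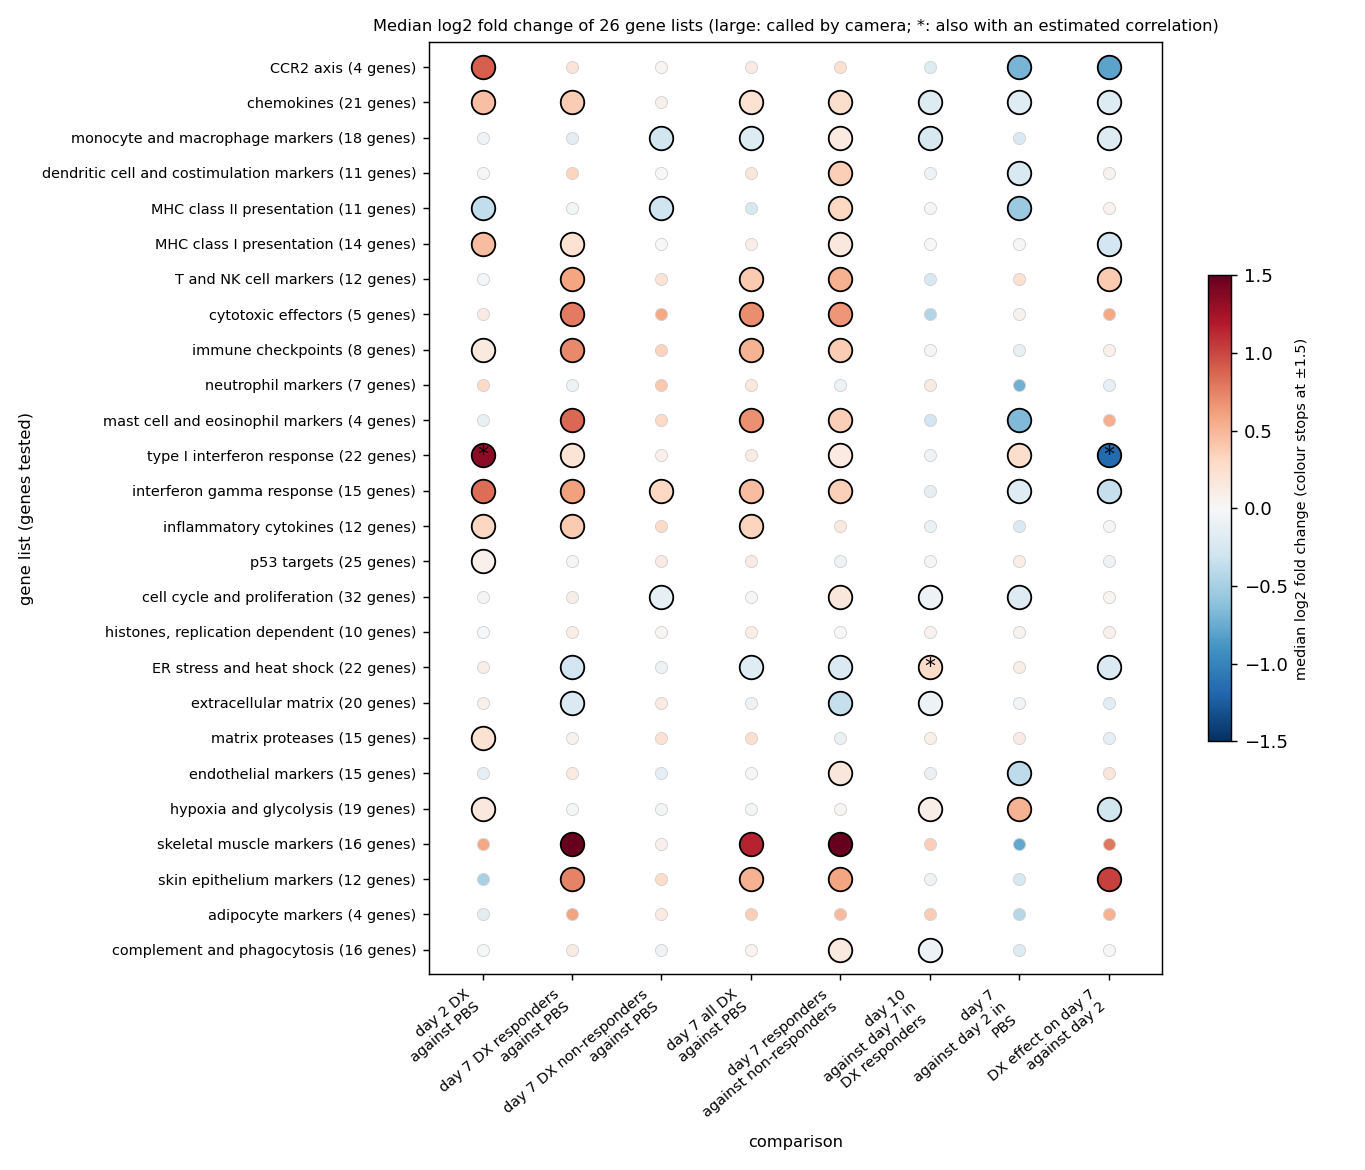
Median log2 difference of the 26 tested gene lists (vertical axis, members in brackets) in the 8 comparisons (horizontal axis), as colour from -1.5 to 1.5. Large circles mark lists called by camera and stars those also called with an estimated correlation, which are the type I interferon response on day 2 and in the difference between days, and ER stress and heat shock from day 7 to day 10.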

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

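The tests of the muscle, T and NK cell and interferon patterns weighed here were chosen after their results were seen, while the splits of the samples were fixed before. What drew attention below was a tested difference of the DX effect between day 7 and day 2.

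The DX effect differed between the days for 28 genes and 10 gene lists. The median difference, day 7 minus day 2, was -1.16 for the type I interferon response, -0.81 for the CCR2 axis, -0.36 for the interferon gamma response, -0.27 for MHC class I presentation and -0.20 each for chemokines and for monocyte and macrophage markers. It was -0.29 for hypoxia and glycolysis, -0.23 for ER stress and heat shock, 0.39 for T and NK cell markers and 1.03 for skin epithelium markers. With an estimated correlation only the type I interferon response was called (adjusted p = 0.0364). Within BeadChip 3, with 1 responder, the medians in the same order were -0.59, 0.03, 0.36, 0.02, 0.35 and 0.12, and -0.35, -0.42, 1.08 and 1.04 for the last 4. Of the first 6 medians 5 took the opposite sign. The 0.03 of the CCR2 axis includes Ccr2, which was not detected on day 7. Of its ligands Ccl12 and Ccl2 stayed negative (-0.74 and -0.06) and Ccl7 had 0.13. Leaving out a single array ended 6 of the 10 calls. MHC class I presentation missed without day 2 DX replicate 1 (0.0558) or day 7 PBS replicate 3 (0.0742), and the interferon gamma response without the same arrays (0.516 and 0.301). Chemokines missed without day 2 DX replicate 1 (0.349, median 0.03), day 2 PBS replicate 3 (0.0559) or day 7 PBS replicate 3 (0.0904). T and NK cell markers missed without day 2 DX replicate 2 (0.181), day 2 PBS replicate 1 (0.0741), non-responder replicate 2 (0.0587) or day 7 PBS replicate 1 (0.104). Monocyte and macrophage markers missed without any of 7 arrays (0.0587 to 0.301): day 2 DX replicate 2, day 2 PBS replicates 1 and 3, non-responder replicates 1 and 2, responder replicate 2 or day 7 PBS replicate 3. Skin epithelium markers missed without any of 6 (0.0707 to 0.331): day 2 DX replicate 2, day 2 PBS replicate 3, non-responder replicate 2, responder replicate 3 or day 7 PBS replicates 1 and 2. Of the named genes 9 had a smaller effect on day 7, 7 of them in the type I interferon list and the others Ifi205 and Trex1, a DNase that limits DNA sensing: Mx1 (-2.31), Ifi205 (-1.75), Isg15 (-1.68), Oasl1 (-1.48), Ifit2 (-1.35), Irf7 (-1.35), Trex1 (-1.29), Usp18 (-1.28) and Ifit3 (-1.07). The difference was positive for the globin genes Hbb-bs (4.16), Hbb-bt (3.90) and Hba-a1 (3.62), which were lower after DX on day 2 (-2.92, -2.72 and -2.54) and not called on day 7 (1.24, 1.18 and 1.08). It was also positive for Tmem164 (1.29) and Sntb2 (1.17; 0 of its 2 other probes went the same way), which were called on day 7 (0.88 and 0.97) and not on day 2 (-0.42 and -0.20). Each of the 14 genes missed the threshold without day 2 DX replicate 1.

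Type I interferon response genes were higher in both day 2 DX tumours than in the 3 PBS tumours. The BeadChip as the whole cause is argued against, since the difference of list means was 1.28 ± 0.21 with the BeadChip as a block and 1.27 ± 0.18 without. A greater content of monocytes, macrophages, dendritic, T and NK cells together would raise their markers alike. The 75th percentile of 41 such markers was 0.17 (median -0.04) and the 25th percentile of the interferon genes 0.96. Neutrophil markers were not among the 41, and the mean of their list was 0.11 in day 2 PBS and 0.37 in day 2 DX. Entry of a single leukocyte type is thus not excluded. Induction within cells already present, by DX, may account for the pattern and was not tested against other differences between the 2 sets of tumours. It rests on 2 DX arrays, and on single genes largely on replicate 1.

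T and NK cell markers were higher in day 7 responders than in PBS tumours. Muscle tissue carried along in replicate 3 is argued against as the source, since the list median was 0.70 without that array and 0.59 with it. Responder replicates 1 and 2 also had higher muscle list means (-0.14 and -0.69) than the day 7 PBS arrays (-1.48 to -1.28). Adjoining tissue in responders is therefore not excluded. With the BeadChip as a block the difference of list means was 0.58 ± 0.23, and 0.66 ± 0.18 without. Day 7 responders and PBS share only BeadChip 3, with 1 array each (list means 0.60 and -0.36). On BeadChip 1 the responders had 0.53 and 0.27 and the non-responder 0.33. Non-responders on BeadChip 2 had -0.07 and -0.27. The block thus cannot decide whether the BeadChip gave the difference. More lymphocytes per tumour, higher expression per cell, adjoining tissue and the BeadChip may each contribute and stay open. All 10 splits of these 6 arrays are too few for a share under 0.05.

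Skeletal muscle transcripts set apart replicate 3 of the day 7 responders and replicate 3 of the day 10 responders. Muscle tissue in these specimens is a candidate source. On both arrays 16 of 16 markers lay more than 1 log2 unit above the mean of the other 15 arrays, with Pvalb at 13.12 and 13.13 against 5.24. This count restates the observation that prompted it and is no separate test of the source. The mean of each marker on those 15 arrays lay between 4.46 and 7.76. BeadChip 1, on which both arrays lie, is argued against, since the lower of their list means stood 3.08 above the highest of the other 4 arrays on it. Whether smaller tumours were taken with more adjoining tissue was not tested.

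Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05, and the real values are set here beside the highest of the other splits. For responders against PBS they were 66 genes and 0, and 13 lists and 14, with 1 and 2 of 10 splits as large. For non-responders against PBS they were 16 genes and 10, and 4 lists and 10 (1 and 8 of 10 splits). Responders against non-responders gave 0 genes and 0, and 18 lists and 13 (10 and 1 of 10). PBS on day 7 against day 2 gave 79 genes and 0, and 10 lists and 13 (1 and 2 of 10). Day 10 against day 7 gave 1 gene and 120, and 7 lists and 11 (3 and 5 of 10). The split with 120 genes parted day 7 replicate 3 and day 10 replicates 1 and 3, which have the most muscle transcripts, from the other 3, and points to a structure of the samples. Those 3 arrays all lie on BeadChip 1 and 2 of the other 3 on BeadChip 3, and the real comparison gave 0 genes with the BeadChip as a block. For all day 7 DX samples against PBS, with 1 DX group in the fit, 4 of 84 splits gave at least the real 35 genes, a share under 0.05. The highest other split gave 66 genes and set PBS replicates 2 and 3 with non-responder replicate 1, all on BeadChip 2, against the rest, and the real comparison gave 6 genes with the BeadChip as a block. For its lists 21 of 84 splits gave at least the real 11 (highest other 17), so chance is not excluded.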

How the results depend on the processing

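The setting without the muscle-rich responder arrays was chosen after seeing the data, and all others were planned. Over the alternatives 2097 values of named genes kept their side of the threshold and direction, 662 lost the call, 14 gained one, 29 changed sign without passing, and 0 called values changed sign. The gained calls were in Ccl2, Ccl7, Ccl12 and Osr2. Under other normalizations the median log2 difference of all genes lay at most 0.023 from 0, and in the main fit at most 0.031. Quantile normalization, or the nearly equal array medians of the authors' values, largely fixes this in advance. It thus does not show how far the results depend on the processing. Values that follow are counts of called genes, set beside 76 for day 2, 66 for responders, 16 for non-responders and 37 for all DX against PBS, 0 for responders against non-responders, 1 for day 10 against day 7, 79 for PBS over time and 28 for the difference between days. Where no reason is given, the cause was not tested. Dim probes are compressed by the offset, and signal over background limits dim genes such as Ccr2, which, like Ifnb1 and Pfkfb3, had no value under the stricter filter.

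Without background correction the count was 29 in responders, 20 in all DX and 0 on day 10, with normexp 27, 21 and 0, and in the authors' processed values 29, 21 and 0. Without a filter on dim probes it was 51 in PBS over time and 0 on day 10, with more genes tested. With the BeadChip as a fixed block it was 0 in responders, 6 in all DX and 0 on day 10, and as a random block 23 in responders. Without the mean-variance trend it was 45 on day 2, 13 in responders and 8 for the difference between days. With array weights it was 250 on day 2, 89 in all DX, 249 in PBS over time, 74 for the difference between days and 0 on day 10. With the compared groups alone it was 169 on day 2, 138 in PBS over time, 4 in non-responders, 1 between responders and non-responders and 0 on day 10. BeadChip 2 alone gave 2 in non-responders and 2 in all DX, and BeadChip 1 alone gave 0 on day 10, each with fewer arrays. Without the muscle-rich arrays the count was 0 in responders, 24 in all DX and 0 on day 10. Other BeadChips held 1 array on a side and gave values without a test. Leaving out each array in turn gave 11 to 67 on day 2, 0 to 78 in responders, 0 to 52 in non-responders, 0 to 105 in all DX, 0 to 0 between responders and non-responders (574 to 970 at unadjusted p under 0.05), 0 to 1 on day 10, 8 to 57 in PBS over time and 1 to 35 for the difference between days.

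Of the gene lists called by camera (11 on day 2, 13 in responders, 4 in non-responders, 11 in all DX, 18 between responders and non-responders, 7 on day 10, 10 in PBS over time and 10 for the difference between days), an estimated correlation called 1, 0, 0, 0, 0, 1, 0 and 1, and fry 1, 4, 0, 0, 0, 0, 3 and 1. With the BeadChip as a block the counts were 9, 12, 5, 14, 16, 7, 11 and 11. Without the muscle-rich arrays 14 lists were called on day 10 and 10 in responders. Leaving out each array gave 9 to 11, 9 to 14, 3 to 9, 9 to 13, 12 to 19, 1 to 12, 6 to 10 and 7 to 12.

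The replicate numbers of the labels did not pair the samples: deviations of 40 same-numbered pairs correlated from -0.221 to 0.545, 8 of them over 0.1, and the best match had the same number in 26 of 80 cases. With the replicate block 62 genes were called on day 2, 0 in responders (1672 at unadjusted p under 0.05), 13 in non-responders, 23 in all DX, 0 between responders and non-responders, 0 on day 10, 74 in PBS over time and 17 for the difference between days. Lists called with the replicate block numbered 12, 13, 4, 13, 18, 7, 11 and 10 in the same order.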

Other observations

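The 3 gene lists tested here beyond the fixed ones were written after the named genes were seen and before the other members were looked up. The seen genes were left out of each test. Genes called on these same arrays prompted the lists, so their unadjusted p-values are not independent support.

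Mast cell and eosinophil markers also stood higher in day 7 responders than in PBS tumours, with a median of 0.87 over 4 genes (camera adjusted p = 0.00479; adjusted p = 0.159 with an estimated correlation), 0.71 with the BeadChip as a block, 0.93 without the muscle-rich array and 0.76 within BeadChip 3. Hdc, the enzyme that makes histamine, differed by 1.71 and Kit, the stem cell factor receptor, by 1.21. Inflammatory cytokine genes had a median of 0.40 in responders and 0.32 on day 2 (camera adjusted p = 0.00168 and 0.00171; adjusted p = 0.179 and 0.177 with an estimated correlation). With the BeadChip block these medians were 0.30 and 0.28, within BeadChip 3 0.13 and 0.22, and in responders 0.26 without the muscle-rich array. Without day 2 DX replicate 1 the day 2 call ended (0.115). Matrix protease genes had a median of 0.21 on day 2 (camera adjusted p = 0.0027; adjusted p = 0.0813 with an estimated correlation), 0.27 with the block and 0.19 within BeadChip 3. Between day 7 and day 10, hypoxia and glycolysis genes had a median of 0.10 (camera adjusted p = 0.00122; adjusted p = 0.479 with an estimated correlation), -0.02 within BeadChip 1, 0.39 within BeadChip 3 and 0.18 without the muscle-rich arrays, a call that ended without day 7 replicate 1 (0.0695) or day 10 replicate 2 (0.177).

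The sterol enzyme genes Nsdhl, Cyp51, Fdps and Sqle were lower in DX tumours on day 7, and a hypothesis is that cholesterol synthesis genes are lower as a set. The 13 other measured genes of the pathway had a median of -0.39 over all day 7 DX samples, 12 of them negative (camera p = 3.19e-08, and p = 0.00683 with an estimated correlation). Over all genes 0 of the 13 were called, and 4 were lower when adjusted over the list alone. With the BeadChip as a block the median was -0.27. Examples are Pmvk (-0.67), Msmo1 (-0.64), Mvd (-0.54) and Idi1 (-0.49), and 0 of the 13 belong to a fixed list. The median of these 13 genes was -0.46 in responders, -0.34 in non-responders and -0.25 on day 2, and from day 7 to day 10 it was 0.18. These values are in line with a lower activity of the sterol-sensing pathway after DX, which may follow from a change of the tumour cells or of the cell mixture, and the data do not separate these.

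Iars, Xpot and Slc7a3 were lower on day 2 after DX, and a hypothesis is that the transcriptional response to amino acid shortage is lower. Of the 23 other measured genes of that response 0 were called over all genes, and 4 were lower when adjusted over the list alone. The 23 genes had a median of -0.23, 18 of them negative (camera p = 3.56e-06, and p = 0.0327 with an estimated correlation), and -0.25 with the BeadChip as a block. Among them Trib3 differed by -0.72, Shmt2 by -0.62, Mthfd2 by -0.59 and Asns by -0.53. The 18 genes that belong to no fixed list had a median of -0.28 with 15 negative. On day 7 the 23 genes had a median of -0.26 in all DX tumours, -0.22 in responders and -0.20 in non-responders, and neither these values nor the difference between the days was tested. The day 2 values may reflect a lower response in DX tumours on that day. The difference of the DX effect, day 7 minus day 2, had a median of 0.07 over the 23 genes. These medians give no sign that the fall is particular to day 2, which was not tested.

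Fcrls was 4.62-fold lower in day 7 responders, and a hypothesis was that genes of resident macrophages are lower as a set. The 15 other measured genes of such cells had a median of 0.50 with 6 negative (camera p = 0.081, and p = 0.484 with an estimated correlation), which argues against a fall of the set. With the BeadChip as a block the median was 0.19, and the 10 genes in no fixed list had 0.54 with 3 negative.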
